A study of Homo sapiens with 6 samples.

How the data were processed

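RNA was sequenced from 6 samples of MDA-MB-231 M3 cells, 3 control and 3 with knockdown of PRMT1 by siRNA. Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase and made into libraries with a stranded mRNA kit, and read as pairs of 150 bases on an Illumina NovaSeq. The controls are described in the labels only as untreated or control cells, so whether they received a transfection or a control siRNA is not given in the sources used here, and neither is the siRNA sequence. The submitters' processing notes name fastp 0.23.2, STAR 2.7.6a, featureCounts, Subread 1.5.1, edgeR 3.40.2 and the genome build hg38, without saying what each did. The annotation release, the strand setting of the counting and any collapsing of duplicate reads are not given in the sources used here. The authors deposited 1 table of whole-number read counts per gene, not normalized, for 20532 genes with Ensembl identifiers, symbols and coordinates, per the file headers. Total counts per sample ran from 16968563 to 20545995, and 3209 genes had no count in any sample. Of the identifiers, 20472 were found in GENCODE release 44, 11832 of them with the same start and end, and coordinates are printed as the deposited table gives them. There are 28 symbols shared by 2 identifiers each, and identifiers were kept apart in every step.

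Replicates were first compared within groups by a chi-square test of their counts over genes with at least 20 reads in the pair. The ratio of chi-square to its degrees of freedom lay between 1.05 and 1.38 (p between 4.40e-178 and 0.000129), where sampling noise alone gives 1. No pair agreed within sampling noise, but the excess was small. The common dispersion from edgeR was 9.77e-05, the lowest value its default search allows, so it is a floor and not a measured spread. All 6 samples were used as separate replicates because the labels call them so, and this small spread may be technical. Genes with too few counts were removed with edgeR's filterByExpr, which left 13710. The groups were compared in R 4.3.3 with edgeR 4.0.16: TMM scaling, a quasi-likelihood fit (glmQLFit) and test (glmQLFTest) with default settings, and Benjamini-Hochberg adjustment over all tested genes at a threshold of 0.05. Log2 fold changes are siPRMT1 minus control, a negative value being lower after knockdown. The standard error of each was computed from the fold change and its F statistic, and levels are TMM-scaled CPM. A second count was restricted to log2 fold changes of at least 1 in size.

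The test, the 31 gene lists, the rule for the named genes and all alternatives except 2 were set before the data were examined. The rule took PRMT1, then the 12 highest and 12 lowest log2 fold changes among genes past the threshold with a mean of at least 10 CPM, an established symbol and no overlap between the groups. From each list with enough changed members it took up to 4 genes with the smallest adjusted p, and the other arginine methyltransferase genes were named with their values. Members that moved against the majority of a list that leaned 1 way are named besides, as are single members that did not pass. Some genes that the rule takes are not reported here. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log-CPM with a prior count of 2 and a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over 30 lists. Alternatives were an estimated correlation and fry. The lists were the PRMT family, interferon-stimulated genes, MHC class I presentation, NF-kB, bone metastasis, TGF-beta, mesenchymal, epithelial, G1/S, G2/M, p53, homologous recombination and Fanconi, RNA-binding proteins with RGG or SR domains, cholesterol, integrated stress response, endoplasmic reticulum chaperones, hypoxia and glycolysis, NRF2, YAP and TEAD, Notch, Wnt, MAPK, collagens, cytosolic ribosomal proteins, nuclear oxidative phosphorylation, mitochondrially encoded genes, histones, and markers of leukocytes, endothelium, bone cells and luminal breast.

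Alternatives for the whole comparison were DESeq2-type size factors (RLE), upper-quartile scaling, library size alone, DESeq2 1.42.0, limma-voom, robust edgeR estimation, no filter, a stricter filter of at least 1 CPM in 3 samples, the replicate number as a block, and leaving out each sample in turn. A pair was added after seeing the data. The first was glmTreat, which tests against a 2-fold change. The other was a correction for GC content and transcript length, in which splines with 5 degrees of freedom on each property were fitted per sample and removed as offsets. GC content and length came from the canonical transcript in GENCODE release 44 and were known for 13689 of the 13710 tested genes.

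A scan for short motifs was also added after seeing the data, in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. It took 12143 genes with an annotated 3' UTR of at least 50 bases and at least 2 CPM. The log2 fold change was regressed on expression level, on GC content and length of the transcript, coding sequence and 3' UTR, and on base and 2-base frequencies. The remainder was tested against the presence of each of 15889 motifs of 7 bases found in at least 100 genes. The scan was repeated in 2 random sets of 6071 and 6072 genes, where the motif with the lowest z in either set was measured in the other.

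The main test, DESeq2, limma-voom and the correction were tested on simulated counts drawn from the means and library sizes of this comparison, with 200 genes changed. For camera, counts were drawn the same way, without those 200 genes. Either the members of 1 list were shifted by 1 on the log2 scale, or a trend alone was added. For the motif scan, the remainders of the real log2 fold changes were shuffled over the genes, and a motif effect was added. Over the 13614 genes in the fit, edgeR recovered 92.5% of genes changed by 0.5 on the log2 scale, 98.5% of those changed by 1 and 98.5% of those changed by 2, with 10 false calls. DESeq2 recovered 82.1%, 94.0% and 98.5% with 0 false calls, and limma-voom matched the shares and false calls of edgeR. When a GC and length trend was added to the simulated siPRMT1 samples, edgeR without the correction made 11966 false calls over 13625 genes. With the correction it made 6 over 13606 genes and recovered 91.0%, 100% and 98.5%. Of 3 shifted lists 3 were found. The simulated trend alone made 7 lists pass without the correction and 0 with it. That trend was linear in the same GC content and log length that the correction fits, so its removal was bound to succeed. Simulated counts were also drawn for each gene independently, with far fewer changed genes than the 12243 found in the data. The shares, false calls and list results therefore need not hold for the real samples. All 5 motifs planted with an effect of -0.2 over the 12143 genes ranked 1. Shuffling removed every real link between sequence and fold change, and the lowest z of a motif not planted was -5.06. In the real scan the AT-rich ATATTTT reached -8.26, so these ranks need not hold there.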

Results

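Gene expression was measured by stranded mRNA sequencing in MDA-MB-231 M3 cells, a bone-metastatic derivative of the human triple-negative breast cancer line MDA-MB-231. The 6 libraries fall into 2 groups of 3 biological replicates, control cells and cells given a small interfering RNA against PRMT1 (siPRMT1), the main enzyme for asymmetric dimethylation of arginine in proteins. Total counts were 19645127, 17921097 and 19054466 in the control libraries and 18015827, 20545995 and 16968563 in the siPRMT1 libraries. Mitochondrially encoded genes took between 5.001% and 5.09% of the counts in the control libraries and between 8.64% and 8.74% in the siPRMT1 libraries, and the 20 most abundant genes took between 8.95% and 9.07% against between 13.2% and 13.3%. The single comparison asks which transcripts differ when PRMT1 is knocked down.

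PRMT1 was lower in every siPRMT1 library. All 75 cytosolic ribosomal protein genes and 45 of 49 nuclear genes of oxidative phosphorylation rose, while 18 of 23 YAP and TEAD targets and 17 of 23 bone metastasis genes fell. These 4 lists stood apart from other genes in limma's camera test (Benjamini-Hochberg adjusted p from 6.30e-18 to 0.0257; adjusted p from 0.101 to 0.258 with an estimated correlation). PRMT1 (ENSG00000126457; hg38, chromosome 19, 49675786 to 49688447, plus strand) had 3160, 2991 and 3072 counts in the control libraries and 193, 218 and 181 in the siPRMT1 libraries. Its level fell from 146 ± 2.93 to 11.9 ± 0.0607 CPM (TMM-scaled read counts relative to library size; mean ± SD, n = 3 each), which is 12.3-fold lower. The log2 fold change was -3.62 (SE 0.0451), with an adjusted p = 9.06e-297 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the other protein arginine methyltransferase genes, PRMT7 (1.06), CARM1 (0.75) and PRMT5 (0.53), the main enzyme for symmetric dimethylation, rose, with all values log2 fold changes. After a correction for GC content and transcript length, these rises were 0.67, 0.082 and 0.23. PRMT3 (-1.20) and PRMT6 (-0.58) fell. PRMT2 was higher at 0.23 but lower with scaling by library size alone (-0.090) and after the correction (-0.10), and PRMT9 was lower at -0.30 but higher after that correction (0.35). PRMT8 had 1 count over all libraries. As a list the 8 tested members gave a median of -0.037, with 4 rising and 4 falling, and did not stand apart from other genes (camera, adjusted p = 0.987). Without the filter on low counts the median over 9 members was -0.31.

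**Figure D1:**
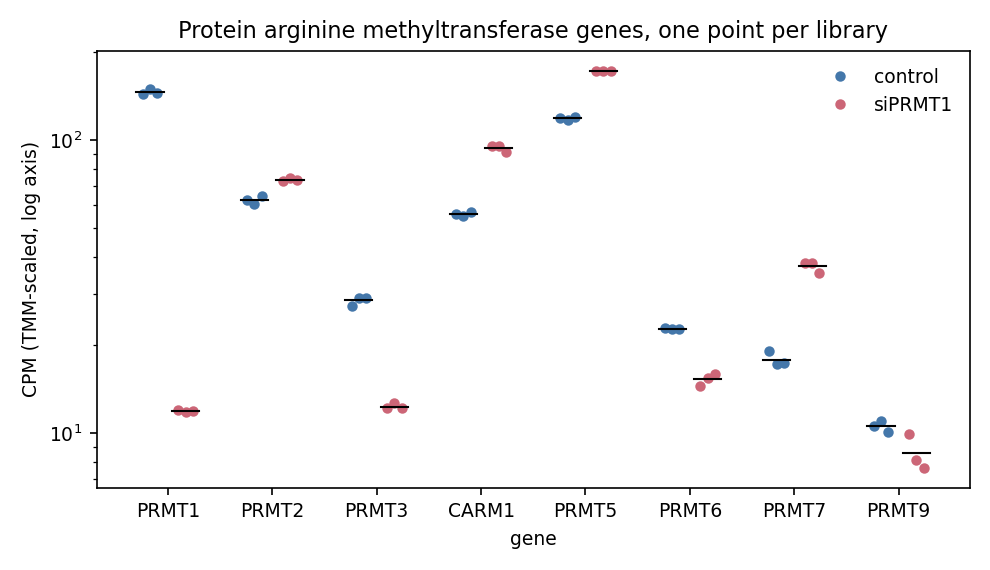
Expression of 8 protein arginine methyltransferase genes, in TMM-scaled CPM on a log axis, with 1 point per library, control and siPRMT1 side by side, and black lines at the group means. PRMT1 lies at a mean of 146 in the control and 11.9 in the siPRMT1 libraries, while the small rise of PRMT2 turns into a fall with scaling by library size alone (-0.090) and after the GC and length correction (-0.10), and the small fall of PRMT9 turns into a rise after that correction (0.35).

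Across the transcriptome, 12243 of 13710 tested genes passed the threshold of 0.05 for the adjusted p, 6078 of them higher and 6165 lower in the siPRMT1 libraries. At least 2-fold changes were found for 4976 genes, 2095 higher and 2881 lower. Levels are relative to the other genes of a library: scaling by library size alone moved the median of all genes by -0.317 on the log2 scale, and the higher share of the changed genes then was 37.7% instead of 49.6%, or 18.5% instead of 42.1% among at least 2-fold changes. The labels call the samples biological replicates without saying whether they came from separate transfections, and the p-values measure only the spread between these samples, which may be technical. Across genes, the fold change followed the base composition and length of the transcript. Genes whose canonical transcript has a GC content under 36% had a median log2 fold change of -1.24 (387 genes), and those above 64% had 1.09 (794 genes). Transcripts shorter than 1000 bases had a median of 1.00 (994 genes), and those longer than 8000 bases had -1.08 (1151 genes). A correction for both properties, chosen after seeing the data, left 11002 genes past the threshold (5487 higher, 5515 lower), 10050 of them also past it without the correction, and 1962 with an at least 2-fold change (654 higher, 1308 lower). Corrected values stand beside the gene groups for this reason. Of the 147 genes named by the fixed rule, 14 had the opposite sign after the correction and 33 were smaller by over 3 times with the same sign, and the corrected value is printed beside those given here.

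**Figure D2:**
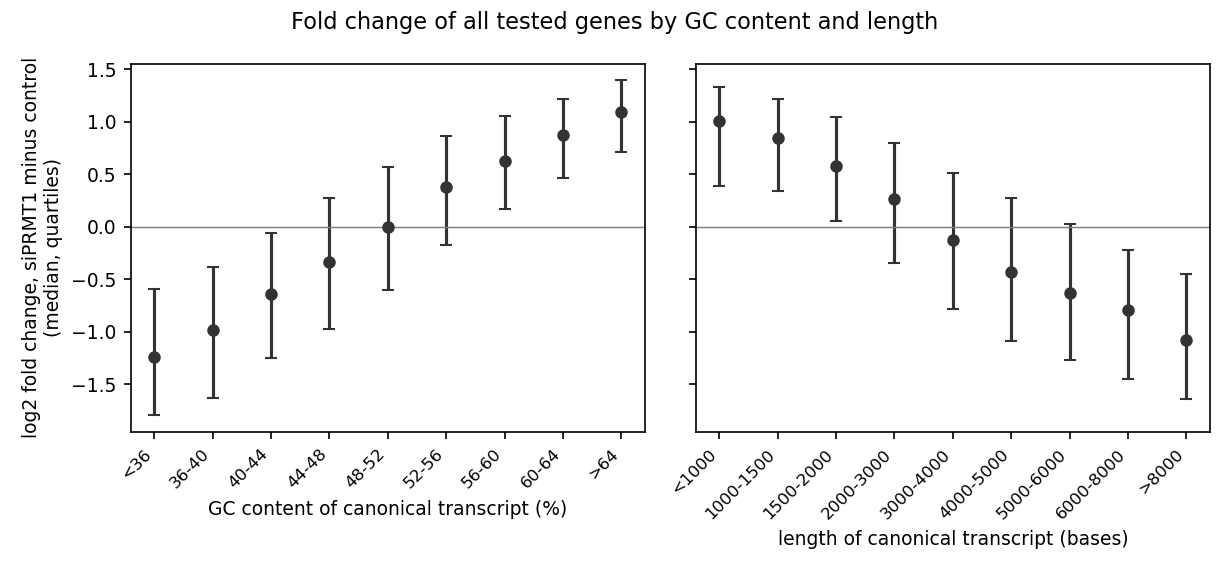
Log2 fold change (siPRMT1 minus control) of tested genes grouped by the GC content in percent (left) and the length in bases (right) of their canonical transcript, with points at the medians and bars from the lower to the upper quartile. Medians run from -1.24 in the group with the lowest GC content to 1.09 in the one with the highest, and from 1.00 in the shortest to -1.08 in the longest transcripts.

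The gene with the highest rise among those named by the fixed rule was SEMA7A, a membrane-anchored semaphorin (ENSG00000138623; hg38, chromosome 15, 74409289 to 74433958, minus strand), which went from 25.5 ± 1.17 to 143 ± 2.21 CPM (SD, n = 3 each). Its log2 fold change was 2.49 (SE 0.0368; adjusted p = 1.63e-261 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). MYL9, a regulatory light chain of myosin in contractile cells, rose from 55.1 ± 1.43 to 234 ± 3.51 CPM, with a log2 fold change of 2.09 (SE 0.0282). The others of the 12 highest rose by log2 fold changes between 2.02 and 2.25. They include the gamma-synuclein gene SNCG (2.25), the ephrin receptor kinase gene EPHA1 (2.16), LMBR1L (2.12), CIMIP2A (2.08), the torsin gene TOR2A (2.07), the AP-1 family transcription factor gene BATF (2.04), the mesotrypsin gene PRSS3 (2.03), CHCHD10 (2.03, 0.53 corrected), which encodes a protein of the mitochondrial intermembrane space, and UBALD1 (2.02, 0.60 corrected). NPIPB12 (2.15) belongs to a family of near-identical copies on chromosome 16, and PRSS3 has close trypsinogen relatives, so their reads can be shared with other genes and both values are uncertain. After the GC and length correction all 12 were still higher, from 0.53 for CHCHD10 to 2.16 for NPIPB12.

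The lowest gene among those named by the fixed rule was CPEB4, which encodes a cytoplasmic polyadenylation element-binding protein that controls translation, and fell from 39.5 ± 1.47 to 2.15 ± 0.0710 CPM (SD, n = 3 each). Its log2 fold change was -4.20 (SE 0.0908; adjusted p = 3.48e-187 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and its relative CPEB2 fell by 3.60 on the log2 scale. SEMA3C, a secreted semaphorin, fell from 168 ± 1.65 to 11.004 ± 0.379 CPM (-3.93), and LIG4, the ligase of non-homologous end joining, from 23.6 ± 2.03 to 1.55 ± 0.133 CPM (-3.92). Others of the 12 lowest are the endosomal lipid kinase gene PIKFYVE (-3.75), the Bardet-Biedl syndrome gene BBS10 (-3.70), the large cadherin gene FAT4 (-3.64), the filaggrin gene FLG (-3.63) and ROR1 (-3.55), a receptor for Wnt ligands. TNKS2 (-3.54), which encodes a tankyrase, NUP58 (-3.53), a nuclear pore gene, and the bicarbonate transporter gene SLC4A7 (-3.51) complete them. All 12 were lower after the GC and length correction, from -2.11 for SLC4A7 to -3.18 for FLG.

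All 75 cytosolic ribosomal protein genes rose, with a median log2 fold change of 1.26, and 64 of them at least 2-fold. RPL28 went from 370 ± 5.24 to 1303 ± 20.4 CPM (1.81), and RPS15 (1.79, 0.54 corrected) rose by a similar factor. The list stood apart from the other genes (limma's camera with a preset correlation and Benjamini-Hochberg adjustment, adjusted p = 6.30e-18; adjusted p = 0.101 with an estimated correlation). After the GC and length correction the median was 0.73, and 74 rose while RPL8 fell (-0.25). Ribosomal protein genes have many processed pseudogenes, so part of their reads may have been assigned elsewhere or lost. Of 49 nuclear genes of oxidative phosphorylation, 45 rose and 3 fell, with a median of 1.01 (camera, adjusted p = 1.85e-08; adjusted p = 0.101 with an estimated correlation) and a corrected median of 0.60. COX6A1 (1.15), COX7C (1.10) and COX6B1 (from 127 ± 4.75 to 358 ± 4.84 CPM), subunits of cytochrome c oxidase, and NDUFS8 (1.61, 0.17 corrected), a subunit of complex I, are examples. The complex I genes NDUFS1 (-0.60), NDUFA5 (-0.23) and NDUFC2 (-0.17) fell; NDUFS1 (0.60) and NDUFA5 (1.14) lay higher after the correction. All 13 mitochondrially encoded genes rose, with a median of 1.31 (camera, adjusted p = 1.16e-04; adjusted p = 0.292 with an estimated correlation) and a corrected median of 1.01. Together they took at least 8.64% of the counts in each siPRMT1 library and at most 5.09% in each control library. MT-ND6 went from 619.8 ± 31.6 to 2028 ± 36.7 CPM (1.71), and MT-CYB (1.49), MT-ND2 (1.45) and MT-CO2 (1.41) rose as well.

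Targets of YAP, a coactivator at the end of the Hippo pathway, and its TEAD transcription factors fell. Of 23 tested members 18 fell and 3 rose, with a median of -1.18 (camera, adjusted p = 8.21e-04; adjusted p = 0.129 with an estimated correlation) and a corrected median of -1.01. MYOF, which encodes the membrane repair protein myoferlin, fell from 642 ± 2.90 to 187 ± 3.61 CPM (-1.78), and CRIM1 from 114 ± 2.83 to 10.8 ± 1.58 CPM (-3.41). The tissue factor gene F3 (-1.47) and PTPN14 (-2.01), a phosphatase that itself restrains YAP, also fell. AXL (0.36), a receptor kinase, and NUAK2 (0.52, 0.10 corrected), a kinase, rose, and FJX1 rose by 0.16 but was lower with scaling by library size alone (-0.15) and after the correction (-0.82). Of 23 tested bone metastasis genes 17 fell and 4 rose, with a median of -1.08 (camera, adjusted p = 0.0257; adjusted p = 0.258 with an estimated correlation) and a corrected median of -0.89. Those that fell include the integrin subunit gene ITGAV (-2.34), the cadherin gene CDH11 (-1.44), the collagen cross-linking enzyme gene LOX (-1.67) and PTGS2, the gene of an inducible cyclooxygenase, which went from 70.7 ± 0.121 to 8.52 ± 0.363 CPM (-3.05). PTHLH (0.87), whose product drives bone resorption by tumours, rose. The collagenase gene MMP1 (0.31) and the follistatin gene FST (0.23) rose but were lower with scaling by library size alone (-0.0054 and -0.088). CSF1 (0.10), a growth factor gene of macrophages and osteoclasts, rose but was lower with that scaling (-0.22) and after the correction (-0.33).

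Epithelial genes rose, with 12 of 16 tested members up and 3 down and a median of 0.86 (camera, adjusted p = 0.0365; adjusted p = 0.328 with an estimated correlation). The keratin genes KRT18, from 255 ± 1.86 to 900.6 ± 5.69 CPM (1.82), KRT8 (1.52, 0.49 corrected), KRT7 (1.42, 0.21 corrected) and KRT19 (1.34, 0.054 corrected) rose. The desmoplakin gene DSP (-1.93) and the tight junction genes CLDN1 (-0.62, -0.013 corrected) and OCLN (-0.56; 0.60 after the GC and length correction) fell, and the E-cadherin gene CDH1 (-0.20, 0.22 corrected) did not pass. After the GC and length correction the median was 0.086 and the list no longer passed (adjusted p = 0.343). KRT8 and KRT18 have many pseudogenes, which makes their values uncertain. Of 10 tested luminal breast markers 8 rose, among them SPDEF (1.16; -0.021 after the correction) and MLPH (0.32; 0.0012 with scaling by library size alone), and the transcription factor gene GATA3 fell (-0.70). The list's median was 0.71 and its corrected median 0.22, and it did not pass (camera, adjusted p = 0.0597). The luminal median was 0.39 with scaling by library size alone, and 0.20 over the 14 members tested without the filter on low counts. Among 20 tested mesenchymal genes 10 rose and 9 fell; the median was 0.15, but -0.16 with scaling by library size alone and -0.24 after the correction, the mean was -0.32, and camera pointed up without passing (adjusted p = 0.881). FN1, the fibronectin gene, fell (-1.61), CD44 fell (-0.72) but was higher after the correction (0.027), and S100A4 (0.91, 0.26 corrected) and ITGA5 (0.90) rose.

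The NF-kB, MAPK, Wnt and hypoxia lists each had more members that fell than rose, and with the filter on low counts they passed after the correction but not before it. Of 24 tested NF-kB cytokines and regulators 17 fell and 5 rose, with a median of -0.63 and a corrected median of -0.62. Camera gave an adjusted p = 0.0774 (0.309 with an estimated correlation), and 2.71e-04 after the correction (0.0999 with an estimated correlation). Without the filter on low counts the list passed too (camera, adjusted p = 0.0358). The superoxide dismutase gene SOD2 (-1.54, -0.30 corrected), the apoptosis inhibitor gene BIRC3 (-2.17) and the interleukin-8 gene CXCL8 (-1.78) fell. The non-canonical pathway genes RELB (1.10, 0.044 corrected) and NFKB2 (0.94, 0.23 corrected), the inhibitor gene NFKBIE (0.95, 0.077 corrected), CSF3 (0.83, -0.31 corrected) and ICAM1 (0.14; -0.18 with scaling by library size alone and -0.30 corrected) rose. Of 23 tested MAPK and immediate early genes 17 fell and 5 rose, with a median of -0.87 and a corrected median of -0.74. The adjusted p by camera was 0.0597 (0.322 with an estimated correlation), and 2.71e-04 after the correction (0.0999 with an estimated correlation). This list also passed without the filter (adjusted p = 0.0358). The feedback phosphatase genes DUSP6 (-1.42) and DUSP4 (-0.90), the ETS factor gene ETV1 (-1.79, -0.50 corrected) and SPRED1 (-1.79, -0.38 corrected), an inhibitor of the pathway, fell. ETV4 (1.38), FOSL1 (0.90, -0.13 corrected), IER2 (0.85, -0.21 corrected), IER3 (0.55, -0.61 corrected) and DUSP5 (0.25; -0.068 with scaling by library size alone and -0.31 corrected) rose. Of 15 tested Wnt targets 10 fell and 2 rose, with a median of -0.44, a corrected median of -0.51 and a median of -0.26 over the 17 tested without the filter. By camera the adjusted p was 0.0961 (0.419 with an estimated correlation), and 0.0383 after the correction (0.267 with an estimated correlation). The Wnt receptor gene FZD7 (-1.64), SOX9 (-1.31), MYC (-0.83) and CCND1 (-0.24, -0.038 corrected) fell, and TCF7 (0.95) and SP5 (0.53, -0.63 corrected) rose. Of 30 hypoxia and glycolysis genes 18 fell and 9 rose, with a median of -0.32 and a corrected median of -0.48. Here camera gave an adjusted p = 0.262 (0.413 with an estimated correlation), and 0.0169 after the correction (0.166 with an estimated correlation). The glycolytic genes GAPDH (1.19, 0.17 corrected), TPI1 (1.03, 0.18 corrected) and ALDOA (0.95, -0.20 corrected) rose, while the hexokinase gene HK2 fell (-2.20).

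**Figure D3:**
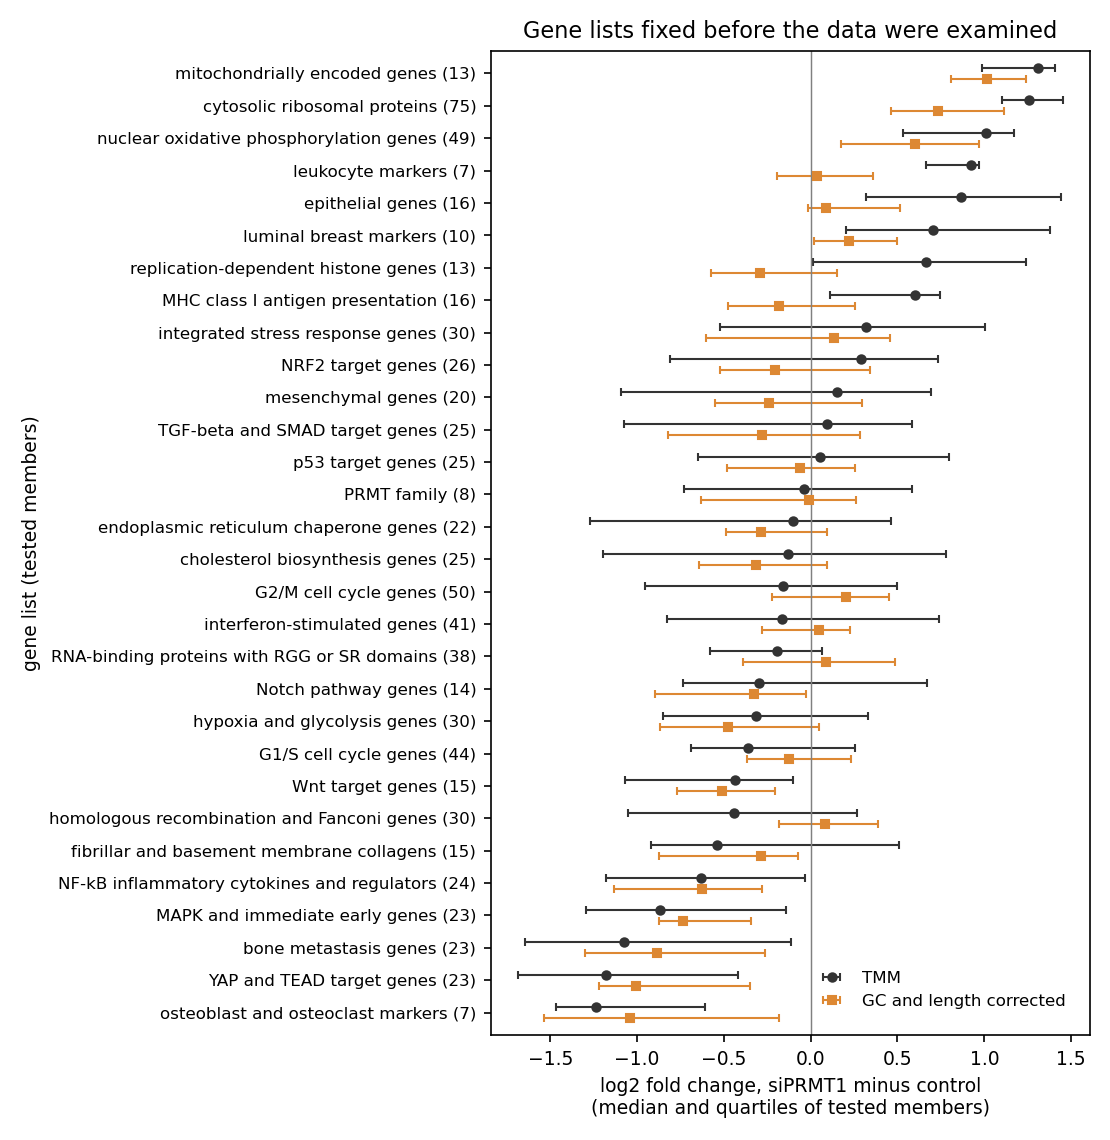
Median log2 fold change (siPRMT1 minus control) of each gene list with at least 5 tested members, with bars from the lower to the upper quartile of the members, after TMM scaling (circles) and after the further GC and length correction (squares). The ribosomal protein, nuclear oxidative phosphorylation and mitochondrially encoded lists lie to the right (1.26, 1.01 and 1.31, corrected 0.73, 0.60 and 1.01) and the YAP and TEAD list to the left (-1.18, corrected -1.01), while 10 other lists lie on the opposite side of 0 after the correction, and the TGF-beta, mesenchymal, p53, integrated stress response and NRF2 medians are negative with scaling by library size alone.

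Cell cycle and DNA repair genes moved in both directions and their lists did not pass. Of 44 G1/S genes 29 fell and 13 rose (median -0.36, corrected -0.12; camera, adjusted p = 0.0964). The chromatin gene ATAD2 (-2.40) and UHRF1 (-2.54), needed to maintain DNA methylation, fell, while the replication factor genes RFC2 (1.12) and RPA2 (0.83) rose. Of 50 G2/M genes 28 fell and 22 rose (median -0.16, but 0.20 after the correction; camera, adjusted p = 0.521). The topoisomerase gene TOP2A (-1.90), TMPO (-1.72) and the cytokinesis genes ANLN (-2.45) and ECT2 (-1.99) fell. Of 30 homologous recombination and Fanconi genes 18 fell and 8 rose (median -0.44, but 0.081 after the correction; camera, adjusted p = 0.225). NBN (-2.28), part of the sensor of DNA double-strand breaks, and RAD51AP1 (-2.09) fell, and EME1 (1.38) and XRCC3 (1.07, 0.17 corrected) rose. Of 25 tested p53 targets 12 rose and 12 fell; the median was 0.051, but -0.26 with scaling by library size alone, -0.063 after the correction, -0.046 without control replicate 3 and -0.12 without siPRMT1 replicate 3, and 0.18 over 26 without the filter, the mean was -0.084, and camera pointed up (adjusted p = 0.987). BAX rose (1.38, 0.038 corrected), CDKN1A rose (0.70) but was lower after the correction (-0.088), and PMAIP1 (-2.02) and RRM2B (-2.23) fell. Of 13 tested replication-dependent histone genes 8 rose and 2 fell (median 0.66, but -0.29 after the correction; camera, adjusted p = 0.225). H2BC12 (1.24, 0.15 corrected) and H1-2 (1.26, 0.17 corrected) rose, H2BC5 rose (0.56) but was lower after the correction (-0.29), and H2BC4 (-1.26) and H2AC11 (-0.46) fell. Histone genes are close copies of each other and their values are uncertain.

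Interferon and antigen presentation genes did not pass as lists with the filter on low counts. Of 41 interferon-stimulated genes 22 fell and 16 rose (median -0.16, but 0.048 after the correction; camera, adjusted p = 0.664). BST2 (1.37, 0.21 corrected), IFI27 (1.43, 0.22 corrected) and OASL (1.32, 1.27 corrected), all antiviral effectors, rose, and ISG15 rose (1.29) but was lower after the correction (-0.14). Of 16 MHC class I presentation genes 13 rose and 3 fell (median 0.60, but -0.18 after the correction; camera, adjusted p = 0.0574, but 0.0293 without the filter). The peptide-loading gene TAPBP (0.74), the immunoproteasome gene PSMB8 (1.21, 0.24 corrected) and HLA-E (0.70, 0.21 corrected) rose, HLA-C rose (0.72) but was lower after the correction (-0.44), and the peptidase genes ERAP1 (-1.06, -0.34 corrected) and ERAP2 (-0.46) and the transporter gene TAP2 (-0.52, -0.030 corrected) fell, with ERAP2 higher after the correction (0.49). Reads of HLA genes can be shared between them, so these values are uncertain.

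Several pathway lists were split. Of 25 tested TGF-beta and SMAD targets 13 rose and 12 fell; the median was 0.095, but -0.22 with scaling by library size alone and -0.28 after the correction, the mean was -0.20, and camera pointed down (adjusted p = 0.987). The thrombospondin gene THBS1 fell from 569 ± 5.19 to 82.4 ± 1.79 CPM (-2.79), and both receptor genes TGFBR1 (-1.42, -0.24 corrected) and TGFBR2 (-1.10) and the ligand gene TGFB2 (-2.06) fell. Of 15 tested collagen genes 9 fell and 6 rose (median -0.54, corrected -0.29, and -0.34 with the stricter filter; camera, adjusted p = 0.536), with COL12A1 (-2.55), COL6A3 (-2.57) and COL13A1 (-0.68) lower and COL1A1 (1.70) higher. Of 14 tested Notch pathway genes 7 fell and 5 rose; the median was -0.30 and the corrected median -0.33, but the median was 0.080 over the 21 members tested without the filter on low counts and 0.039 over the 16 tested without siPRMT1 replicate 1 (camera, adjusted p = 0.536). NOTCH2 (-1.95), its ligand gene JAG1 (-1.36) and the coactivator gene MAML2 (-2.02) fell, and RBPJ fell (-0.59) but was higher after the correction (0.59). Of 38 RNA-binding proteins with RGG or SR domains, a class rich in arginine methylation sites, 23 fell and 12 rose (median -0.19, but 0.087 after the correction; camera, adjusted p = 0.142, but 0.00358 with scaling by library size alone). G3BP2 (-1.54) and HNRNPH1 (-1.22) fell, HNRNPR fell (-1.41) but was higher after the correction (0.11), and FBL (1.36, 0.23 corrected), the gene of the nucleolar methyltransferase fibrillarin, rose.

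Metabolic and stress lists were divided as well. Of 25 cholesterol biosynthesis genes 13 fell and 11 rose (median -0.13, corrected -0.32; camera, adjusted p = 0.618), with HMGCS1 (-2.35), INSIG1 (-1.58) and STARD4 (-2.18) lower and EBP (1.34, 0.43 corrected) higher. Of 30 integrated stress response genes 17 rose and 11 fell; the median was 0.32, but -0.00069 with scaling by library size alone, and the corrected median was 0.13 (camera, adjusted p = 0.392). The regulator gene ATF4 (1.32) and SARS1 (1.07) rose, the amino acid transporter gene SLC7A5 fell (-0.77), and SLC3A2 rose (0.82) but was lower after the correction (-0.094). Of 22 endoplasmic reticulum chaperone genes 13 fell and 7 rose (median -0.10, corrected -0.29; camera, adjusted p = 0.363). The calnexin gene CANX fell from 1631 ± 10.1 to 479.7 ± 1.21 CPM (-1.77), EDEM1 (-1.98) and SEL1L (-1.76, -0.52 corrected), which act in degradation of misfolded proteins, fell, and the calreticulin gene CALR rose (0.69, 0.063 corrected). Of 26 NRF2 targets 15 rose and 10 fell; the median was 0.29, but -0.027 with scaling by library size alone and -0.20 after the correction, the mean was -0.048, and camera pointed up (adjusted p = 0.521). The thioredoxin reductase gene TXNRD1 fell (-2.13), TXN (0.89) and TKT (0.96) rose, and the ferritin gene FTL rose (1.03) but was lower after the correction (-0.051).

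Marker lists of other cell types had few tested members. Of 7 tested leukocyte markers 6 rose, with a median of 0.92 and a corrected median of 0.034 (camera, adjusted p = 0.0602, but 0.0297 with scaling by library size alone). They include CD68, at 201 ± 2.07 CPM in the control libraries (0.89, 0.034 corrected), LAPTM5 (0.45) and CSF1R (0.92), and CD14 rose (0.94) but was lower after the correction (-0.32). Of 7 tested osteoblast and osteoclast markers 5 fell and 1 rose (median -1.24, corrected -1.04, but -0.022 over the 11 members tested without the filter on low counts; camera, adjusted p = 0.392), with ATP6V0D2 (-1.31), CALCR (-1.95) and SOST (-1.24) lower and BGLAP (1.83, 0.54 corrected) higher. Levels of CALCR, SOST and BGLAP were low, at no more than 3.35, 4.47 and 4.14 CPM in any library. CALCR lay between -2.20 and -1.67 when 1 sample was left out. Of 3 tested endothelial markers ESAM rose (1.36, 0.45 corrected), KDR fell (-3.00) and PECAM1 (-0.070, 0.50 corrected) did not pass, too few for a test of the list. KDR and CD14 were also low, at no more than 5.08 and 8.59 CPM in any library. Adjusted over the list alone, 30 of the 31 lists had the same counts of rising and falling genes as over all genes tested, and in the histone list 8 rose and 1 fell.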

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

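The GC and length correction and the test against a 2-fold change were chosen only after the results were seen. The number of changed genes (12243) lay between 11002 and 12532 over all alternatives and between 12069 and 12159 when 1 sample was left out. The number with an at least 2-fold change (4976) lay between 4793 and 5363 over the alternatives set beforehand and between 4987 and 5099 when 1 sample was left out, and was 4111 by glmTreat but 1962 after the correction, which removes the part of the fold changes that follows GC content and length. PRMT1 lay between -3.63 and -3.60 when 1 sample was left out and at -4.73 after the correction. Samples with the same replicate number did not deviate together (r over genes of -0.0173, -0.0274 and -0.0169). The deviations within a group are close to sampling noise, so r could lie near 0 for paired samples too, and this does not settle pairing. With the number as a block 12219 genes passed, 4980 at least 2-fold. Of the named genes' values under the alternatives set beforehand, 2203 kept their direction and their side of the threshold, 1 turned (PRMT2, -0.090 with scaling by library size alone) and 1 lost the threshold (MLPH, 0.0012, same scaling). After the correction 131 kept both, BAX (0.038) and CD68 (0.034) lost the threshold, and 14 turned: ISG15 (-0.14), HLA-C (-0.44), CD44 (0.027), CDKN1A (-0.088), HNRNPR (0.11), SLC3A2 (-0.094), ALDOA (-0.20), FTL (-0.051), RBPJ (0.59), H2BC5 (-0.29), CD14 (-0.32), SPDEF (-0.021), PRMT2 (-0.10) and PRMT9 (0.35). Lists past the threshold numbered 6, 8 with library size alone, 9 without the filter, 9 after the correction, 0 with an estimated correlation and 30 by fry, which asks whether a list's genes move 1 way on balance and not whether they differ from other genes; by fry the interferon list pointed up, against its median, and the TGF-beta, p53 and mesenchymal lists down, against theirs. List medians that turned were, with library size alone, TGF-beta (-0.22), mesenchymal (-0.16), p53 (-0.26), integrated stress response (-0.00069) and NRF2 (-0.027); without the filter, Notch (0.080); and after the correction, interferon (0.048), MHC class I (-0.18), TGF-beta (-0.28), mesenchymal (-0.24), G2/M (0.20), p53 (-0.063), homologous recombination and Fanconi (0.081), RGG or SR (0.087), NRF2 (-0.20) and histones (-0.29). When 1 sample was left out, the p53 median lay between -0.12 and 0.24 (below 0 without control 3, at -0.046, or siPRMT1 3, at -0.12), the Notch median between -0.29 and 0.039 (above 0 without siPRMT1 1) and the PRMT family's between -0.094 and 0.0010 (above 0 without siPRMT1 3). Library size alone adds 1 shift to all genes and the unfiltered Notch list holds more genes; for the other turns the cause was not tested. At these depths the median standard error of a log2 fold change was 0.0549.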

Other observations

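The tests in this part were chosen only after the results were seen. Genes were also grouped by the stem of their symbols, giving 52 families of at least 20 tested members. Mitochondrial ribosomal protein genes rose: 43 of 49 genes of the large subunit (MRPL) rose and 3 fell, with a median log2 fold change of 1.02 (camera, adjusted p = 1.38e-06; adjusted p = 0.166 with an estimated correlation), 0.70 with scaling by library size alone and 0.40 after the GC and length correction (adjusted p = 1.04e-04; adjusted p = 0.561 with an estimated correlation). MRPL12 went from 68.6 ± 2.03 to 209 ± 2.93 CPM (SD, n = 3 each), a log2 fold change of 1.61 but only 0.145 corrected. MRPL51 went from 113 ± 4.13 to 279.9 ± 4.54 CPM (1.32, 0.93 corrected), while MRPL42 (-0.72), MRPL19 (-0.59) and MRPL30 (-0.14) fell. In the small subunit (MRPS) 24 of 28 rose and 4 fell, with a median of 0.58 (camera, adjusted p = 0.00195; adjusted p = 0.299 with an estimated correlation), 0.26 with library size alone and 0.36 after the correction (adjusted p = 0.0826). MRPS30 (-0.57), MRPS10 (-0.38), MRPS25 (-0.23) and MRPS27 (-0.12) fell.

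Genes of nuclear pores, centrosomes and deubiquitinating enzymes mostly fell before the GC and length correction. Of 22 nucleoporin genes (NUP) 19 fell, with a median of -0.55 (camera, adjusted p = 0.00731; adjusted p = 0.2496 with an estimated correlation), and NUP153 went from 113 ± 1.39 to 20.04 ± 0.993 CPM, while NUP88 (0.28) and NUP85 (0.17) rose. Of 38 centrosomal genes (CEP) 28 fell and 7 rose, with a median of -0.59, but 0.12 after the correction (camera, adjusted p = 0.0184; adjusted p = 0.299 with an estimated correlation), and CEP170 went from 104 ± 3.33 to 13.2 ± 0.757 CPM. Of 47 ubiquitin-specific protease genes (USP) 36 fell and 8 rose, with a median of -0.71 (camera, adjusted p = 0.00195; adjusted p = 0.166 with an estimated correlation), and USP34 went from 80.2 ± 0.553 to 19.99 ± 1.37 CPM. None of these 3 families passed after the GC and length correction: the medians were -0.011 for NUP, 0.12 for CEP and -0.043 for USP (adjusted p = 0.778, 0.663 and 0.778). Scaling by library size alone moves the median of all genes by -0.317, so with it the medians of all 3 could only fall further (-0.87, -0.91 and -1.02).

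The fold change rose with the GC content of a transcript (Spearman's rho 0.648 across genes, which are not independent replicates) and fell with its length (-0.558), and splines on both took 52.1% of the variance. Between siPRMT1 and control samples the slope on GC content was at least 0.718 log2 units per 10% GC, and between samples of 1 group it was at most 0.0315. Sequencing depth is excluded as the cause, since the slope between the deepest and the shallowest siPRMT1 sample was -0.000118. A difference between the groups in RNA quality or library preparation may have produced the trend, as may an effect of PRMT1 loss on RNA processing or decay, and the slope of 0.0315 within groups does not separate them, since either would leave the samples of a group alike. An effect of transfection, or of the siRNA on other transcripts, would also leave the samples of a group alike. The labels give no batch and do not say that the controls were transfected, so these explanations cannot be told apart for this trend.

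The trend was also set against the 6 lists that passed. After the correction 5 kept their direction and passed with camera's preset correlation. Their medians were 0.73 for ribosomal proteins, 0.60 for nuclear oxidative phosphorylation, 1.01 for mitochondrially encoded genes, -1.01 for YAP and TEAD targets and -0.89 for bone metastasis genes. With an estimated correlation none of the 5 passed (camera, adjusted p = 0.0936, 0.0936, 0.166, 0.0936 and 0.0999). The correction covers GC content and length of the whole canonical transcript only, and a trend on parts of the transcript may remain. The part it covers does not account for these medians in full, but the trend as the whole cause is not excluded. For epithelial genes the median went from 0.86 (quartiles 0.32 and 1.44) to 0.086 (quartiles -0.016 and 0.51) and the call ended because the members moved towards 0, so the trend may account for that list. The correction would also remove a biological effect that follows GC content or length, and a fault that acts on other properties of RNA stays open for all 6, as does an effect of transfection, since the labels do not say that the controls were transfected; a response to loss of PRMT1 was not tested apart from these. All 10 splits of the 6 samples were fitted with edgeR, too few for a share under 0.05, and no other tool was run on the splits. The real split (1 of 10) gave 12243 changed genes. The highest of the others gave 0, with between 7 and 20 genes at an unadjusted p under 0.05. Every other split mixes siPRMT1 and control samples, so the large difference between the groups became spread within them. Few calls were bound to follow there, and the splits say nothing about chance.

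Genes with the motif TGGAACA in the 3' UTR were lower by a small amount: the motif ranked 1 of 15889 by z, with an effect of -0.19 (SE 0.0174; 1680 genes) beyond GC content, length, expression level and base frequencies. Chosen by its z in either of 2 random sets of the genes, it ranked 1 in the other set too, with a z of -6.34 and -6.44 SDs from the mean of other motifs of the same bases there, and its reverse complement had an effect of 0.0059 (SE 0.0173), so base composition of the 3' UTR is excluded as its cause. In PRMT1 the reverse complement TGTTCCA lies once, in exon 5 (hg38, chromosome 19, from 49682202), and TCTGATT, the lowest of 1216 motifs that PRMT1 carries as written (-0.13, SE 0.0166; 2161 genes), ends 19 bases on at 49682220, as 1.13% of such pairs do within 21, but it ranked 5 of all motifs (z -7.777), below the AT-rich ATATTTT (-8.26), GATTTTT (-7.83) and TAATGTT (-7.783), and was chosen in only 1 of the 2 sets (TGTGTTT in the other), so base composition stays open for it. The reverse complement of TCTGATT had an effect of 0.014 (SE 0.0173), which does not settle base composition for a motif chosen in only 1 set. These positions may mark the siRNA, with seed pairing of its strands to other transcripts as a candidate explanation. For the second motif it rests on the 19 bases alone, and the siRNA sequence, not given in the sources used here, would test it. In the 3' UTR the 2 motifs add 0.522% of the variance. Among 8836 genes with neither motif there 33.7% changed at least 2-fold, against 41.4% of 3307 with either. These shares were not adjusted for any covariate of the scan. Among the covariates, 3' UTR length went with the fold change (Spearman's rho -0.507 across genes). Sites in the coding sequence also had effects of -0.10 (SE 0.0146, TGGAACA, 2671 genes) and -0.068 (SE 0.0209, TCTGATT, 1077 genes).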
